A study of Mus musculus with 6 samples.

How the data were processed

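The data are RNA counts of marrow cells sorted for high activity of aldehyde dehydrogenases, 3 samples from female and 3 from male mice, grouped by the sex and replicate number in the sample titles. Per the labels' protocols, total RNA was extracted with TRIzol and a column kit, and libraries were made by BRB-seq: each sample was reverse transcribed with its own barcoded oligo-dT primer, samples were mixed and amplified by PCR, and read 1 carried a molecular identifier (UMI) and the barcode while read 2 carried the insert. Such reads come from the 3' ends of transcripts. Per the submitters' processing notes, the tools named were UMI-tools, Trim Galore 0.6.7, HISAT2 2.2.1, featureCounts 2.0.1 and DESeq2, with the builds GRCm38 and GRCh38, and no role or order is given for them. The authors deposited a table of raw counts per gene, whole numbers with no normalisation, per the file headers and the values. Whether reads with the same molecular identifier were collapsed, and whether counting used strand, is not given in the sources used here, so counts may hold PCR copies, and overlapping or antisense genes may share reads. A list of barcodes deposited with the counts, per the file headers, names 16 samples in 1 pooled library, of which 6 are the samples here and 10 are lung samples not analysed here.

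Gene identifiers were matched to GENCODE M21 (GRCm38): all 21606 had coordinates and 0 lay on another chromosome than the table gives, while 311 symbols differed. Symbols are those of the table and coordinates those of the annotation. Totals ran from 679724 to 1475224 counts, with a median of 1039812.5, and were 1.65 times as large in females on average. Counting intervals are exact 95% binomial intervals of the ratio of summed counts per library size scaled by TMM (below). In the closing section they are of the ratio of raw summed counts. A floor of 3 counts over a group stands for 0, and for Cxcl2 without female replicate 2 it was taken per library total. Intervals and floor cover counting error only. Within each sex no library was a copy of another: between 165 and 348 genes had the same count in a pair, and the counts differed by more than counting error, with chi-square per degree of freedom from 2.15 to 4.63.

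Genes were kept with edgeR 4.0.16 in R 4.3.3 by filterByExpr with the sex as group (minimum count 10, minimum total 15), which left 8460 genes and took out 13146. Counts were scaled by TMM and male minus female was tested with edgeR's quasi-likelihood F test, with no covariate, and Benjamini-Hochberg adjustment at 0.05 over all tested genes. The common biological coefficient of variation was 0.102. The standard error of a log2 fold change is the fold change divided by the root of F. CPM are normalised by TMM library sizes, and means are given ± SD over 3 libraries. Gene lists with at least 5 tested genes were tested with camera (limma 3.58.1) at a preset correlation of 0.01 and with an estimated correlation, adjusted over 22 lists; lists with fewer have gene values only. Of 29 lists fixed before the data were examined, 28 were written out and the ribosomal proteins were taken by symbol. They cover Y-linked genes, X-inactivation RNAs, X-linked escape genes, aldehyde dehydrogenases, retinoid handling, 11 sets of cell type markers, angiogenic factors, cytokines, sex steroids, interferon-stimulated genes, MHC class II, immediate-early and heat-shock genes, both cell cycle phases, glycolysis, oxidative phosphorylation, antioxidants and mitochondrially encoded genes. Lists of plasma cell, mature B cell, early B and lymphoid progenitor, erythroid and megakaryocyte progenitor, and lung epithelial genes were written after the data were seen.

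The genes named were set by a rule fixed before the data were examined. It takes all tested genes of the Y-linked, X-inactivation and X-linked escape lists, and outside these the 10 largest changes in each direction among genes past the threshold whose libraries do not overlap between the sexes, leaving out predicted genes. It adds all tested aldehyde dehydrogenases, from each other list up to 4 genes past the threshold by smallest p or, where none passed, the 2 with the highest level, and the 5 genes with the most counts. Egr1, Atf3, Junb, Fos, Dusp1, Zfp36, Nfkbia, Dnajb1, Ighg2b and Sftpc were named after their values were seen. So were, in the closing section, Adgre1, Ermap, Jchain, Mzb1, Sdc1, Fkbp11, Ssr4, Xbp1, Creld2, Edem1 and Txndc5.

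The steps were tested on simulated data with 200 of 8460 genes changed in the male minus female comparison. A list of 20 further genes was raised by 0.5 on the log2 scale. Among the 200, 29.9% of genes changed by 0.5 were recovered, 77.6% of those changed by 1 and 100% of those changed by 2. Of 157 genes called, 10 belonged to neither group and had not been changed. Alternatives were RLE, upper-quartile and library-size scaling, no filter and a stricter one (10 counts in every library of a sex), DESeq2 1.42.0, limma-voom with and without sample weights, an adjusted p under 0.10, a fold threshold of 1 on the log2 scale, the replicate number as a block, leaving out each library, library sizes without the 5 top genes and haemoglobin, thinning to the smallest library, and for lists fry and lists without X and Y genes. Medians of lists were given bootstrap 95% intervals over genes. Figures were drawn with matplotlib 3.10.9.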

Results

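RNA was measured in bone marrow cells of C57BL/6 mice, a common inbred laboratory strain, that had high activity of aldehyde dehydrogenases, a family of enzymes that oxidise aldehydes. High activity of these enzymes is used to sort a fraction of bone marrow rich in progenitor cells, called ALDHbr here. There were 3 libraries from female mice and 3 from male mice, made with BRB-seq, a bulk method in which each sample gets a barcode at reverse transcription and samples are then amplified as a pool. Total counts per library were 1199551, 1475224 and 1285309 in the female replicates 1 to 3 and 837756, 679724 and 880074 in the male ones, so the mean was 1320028 ± 141078 (SD, n = 3) in females and 799185 ± 105598 in males. The table held 21606 genes, of which 8460 had enough counts to be tested. The labels do not say that the replicates came from separate animals, so p-values measure only the spread between these samples, which may be technical.

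All libraries carried the transcripts of immature myeloid cells at high levels. Mpo, which encodes the myeloperoxidase of primary granules, had 7639 ± 224 (SD, n = 3) normalised CPM (counts per 1e+06 counts of the library) in females and 6332 ± 284 in males. Prtn3, a serine protease of the same granules, had 2966 ± 66.8 CPM in females and 2853 ± 272 in males. Cd34, a surface marker of progenitors, had 336 ± 39.1 and 366 ± 44.5 CPM. No gene of the T and natural killer cell list reached the depth needed for a test. The 5 genes with the most counts were the mitochondrial ribosomal RNAs mt-Rnr2 and mt-Rnr1, Actb, Mpo and the immunoglobulin kappa constant gene Igkc, which held 2.54%, 0.778%, 1.78%, 0.712% and 0.684% of all counts.

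The labels were first compared with genes that mark sex. Xist, the X-linked RNA that silences an X chromosome in female cells (chromosome X, 103460366 to 103483254, GRCm38), had 225, 251 and 297 counts in the female libraries and 0, 2 and 0 in the male ones, a female to male ratio of 220 (95% counting interval 60.8 to 1822). Ddx3y and Eif2s3y, Y-linked genes for an RNA helicase and a translation factor, had 0 counts in every female library and 197 and 169 in the male libraries together. Against a floor of 3 counts over the female group, these were at least 115-fold and 98.8-fold higher in males. Uty, another Y-linked gene, had 1 count in females, in female replicate 1, and 46 in males. The fitted log2 fold change of Xist moved from -7.60 to -10.8 without male replicate 2, which held both male counts, and that of Uty from 5.78 to 7.36 without female replicate 1. All 6 libraries matched their labelled sex.

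The comparison of male with female cells asks which genes differ in expression by sex. Genes of the early stress response and chemokines were higher in male cells, led by Ccl4 and Cxcl2, which attract immune cells, the heat-shock genes Hspa1a and Hspa1b, and the transcription factors Klf2, Egr1 and Atf3. Car1 and Car2, carbonic anhydrases abundant in the erythroid lineage, and Pf4, a platelet chemokine, were also higher in male cells. The antibody genes Iglc1, Ighg1, Igha and Ighg2b and the antigen presentation genes Cd74, H2-Aa and H2-Eb1 were higher in female cells. They are 4 of 10 tested constant-region genes of antibodies and 3 of 11 tested genes of the MHC class II list, whose call was lost with an estimated correlation (adjusted p = 0.273). In all, 36 genes were higher in males and 13 in females by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05, and 44 of these 49 lay on neither X nor Y. In each of the 49 genes all 3 libraries of a sex lay above all 3 of the other; over all tested genes this held for 7.57% with males above and 8.03% with females above, where chance gives 5% each. Leaving out single libraries moved the counts, to 332 and 77 genes without male replicate 1, 19 and 4 without male replicate 3, and 24 and 7 without female replicate 2. Male replicate 1 was closer to the female libraries (mean correlation of log2 CPM 0.965) than to the other male ones (0.956). Scaled by library size only, 29 genes were higher in males and 23 in females, so that the share higher in males was 55.8% in place of 73.5%.

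**Figure D1:**
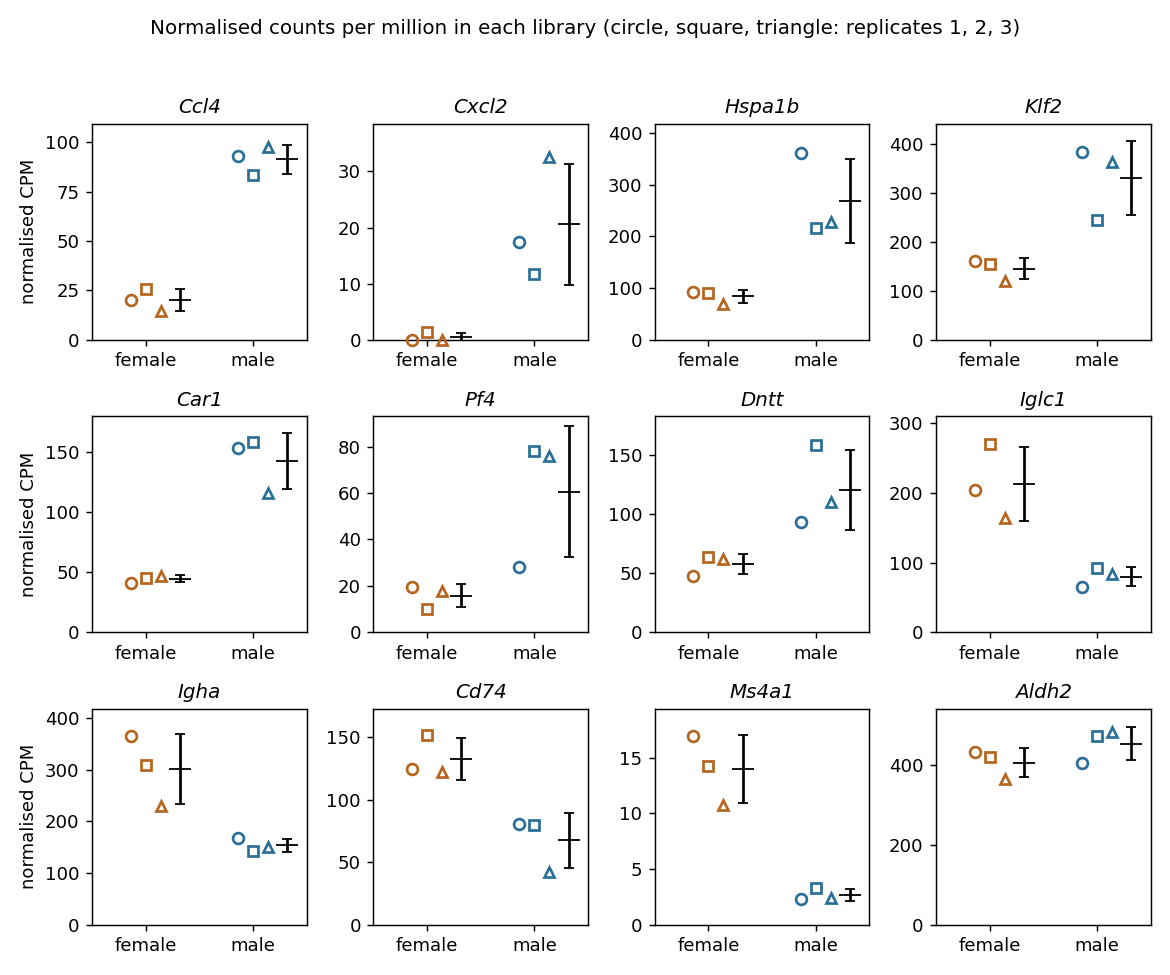
Normalised CPM (vertical axes, linear, from 0) of 12 genes in each of the 3 female and 3 male libraries; open symbols are libraries, and the bar with whiskers is the mean ± SD of a sex. Ccl4, Cxcl2, Hspa1b, Klf2, Car1, Pf4 and Dntt lay higher in every male library, Iglc1, Igha, Cd74 and Ms4a1 lay higher in every female library, and Aldh2 overlapped.

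Of the 24 tested immediate-early and heat-shock genes, 13 rose in males relative to females, none fell, and 11 did not pass (19 rose when adjusted over the list alone). Hspa1b, which encodes an inducible 70-kilodalton heat-shock protein, rose from 83.8 ± 12.7 (SD, n = 3) to 268 ± 80.5 CPM, a log2 fold change of 1.69 ± 0.17 (SE; edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 9.05e-07). Its neighbour Hspa1a on chromosome 17 changed by 1.78 ± 0.20; both copies have nearly identical sequences, so reads could be split between them. Klf2 (log2 fold change 1.20 ± 0.15) rose from 145 ± 21.7 to 331 ± 75.6 CPM, and Dusp2, a phosphatase that switches off MAP kinases, rose by 1.12 ± 0.14. Egr1, Atf3 and Ier3 had log2 fold changes of 1.31, 1.44 and 1.84, and Junb, Fos, Dusp1, Zfp36, Nfkbia and Dnajb1 had smaller ones of 0.77, 0.76, 0.73, 0.74, 0.83 and 0.66. The list as a whole was higher in males (camera, adjusted p = 3.16e-46; adjusted p = 0.0339 with an estimated correlation). Some of the smaller changes did not pass with fewer libraries, although their folds stayed above 0. Without male replicate 3, the log2 fold changes of Nfkbia, Dusp1, Fos, Dnajb1 and Zfp36 were 0.69, 0.70, 0.61, 0.67 and 0.74, and none of the 5 passed (adjusted p = 0.0625, 0.0686 and 0.233 for the first 3 by edgeR's quasi-likelihood test). Dnajb1 and Zfp36 had their highest adjusted p, 0.108 and 0.185, without female replicate 3 (log2 fold changes 0.57 and 0.58), where Fos also did not pass. Dusp1, Fos and Zfp36 did not pass without female replicate 2 either. In raw counts, Fos had 3097 in the female libraries together and 3057 in the male ones, although the male libraries held only 0.605 times as many counts in total.

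Among the 8 tested cytokines and chemokines, 4 rose in males, as they also did adjusted over the list alone, and all 8 fold changes were above 0. Ccl4 (chromosome 11, 83662584 to 83664683, GRCm38) rose from 20.2 ± 5.56 to 91.3 ± 7.40 CPM (n = 3 each), a log2 fold change of 2.17 ± 0.20 (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 2.23e-07). Cxcl2 had 2 counts in females and 49 in males, a ratio of 42.98 (95% counting interval 11.3 to 365). Both female counts were in female replicate 2; without it Cxcl2 was at least 16.9-fold higher in males against a floor of 3 counts over the female group, and its fitted log2 fold change moved from 5.12 to 7.38. Ccl3 rose by 1.24 ± 0.19 and Tnf, the gene of tumour necrosis factor, by 1.36 ± 0.31. Tnf passed only when male replicate 1 was the library left out; leaving out any of the other 5 lost the call, with an adjusted p of up to 0.233 (without male replicate 3) by the same test. The list was higher in males (camera, adjusted p = 3.91e-17; adjusted p = 0.0251 with an estimated correlation). Outside the lists, Rgs1, a brake on G-protein signalling, rose by 2.198 ± 0.27, Dusp5 by 1.72 ± 0.29 and Tnfaip3, an inhibitor of NF-kappa-B signalling, by 1.59 ± 0.34. Dusp5 did not pass without male replicate 3 (adjusted p = 0.0624 by edgeR's quasi-likelihood test), nor Tnfaip3 without male replicate 3 (0.233) or female replicate 3.

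Of the 6 tested erythroid markers, 2 rose, none fell and 4 did not pass (4 rose when adjusted over the list alone). Car1 rose from 44.5 ± 3.04 to 142 ± 23.3 CPM (n = 3 each), a log2 fold change of 1.67 ± 0.15, and Car2 rose by 1.52 ± 0.19, with Benjamini-Hochberg adjusted p = 2.89e-07 and 3.90e-05 by edgeR's quasi-likelihood test. The list was higher in males (camera, adjusted p = 7.66e-13; adjusted p = 0.0469 with an estimated correlation). Pf4, the gene that passed of the 2 tested megakaryocyte and platelet markers (2 adjusted over the list alone), rose by 1.92 ± 0.31, with 15.7 ± 4.89 CPM in females and 60.7 ± 28.4 in males. Cpa3, a protease gene of mast cells and basophils, rose by 1.44 ± 0.28 and was the only one of 6 tested markers of its list to pass (adjusted over the list alone, 3 rose and 2 fell). That list as a whole did not differ (camera, adjusted p = 0.390). Without male replicate 3, neither Pf4 nor Cpa3 passed, with adjusted p = 0.0625 and 0.220 by edgeR's quasi-likelihood test; Cpa3 did not pass without female replicate 2 either.

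Genes of the B lineage moved in both directions. Dntt, the DNA polymerase of early lymphoid cells, rose from 57.6 ± 8.78 to 120 ± 33.7 CPM, a log2 fold change of 1.02 ± 0.18, while Ms4a1, the gene of the B cell surface protein CD20, fell from 13.97 ± 3.08 to 2.69 ± 0.55 CPM. These were the only ones of 7 tested B-lineage markers to pass (1 rose and 2 fell adjusted over the list alone), and the list as a whole did not (camera, adjusted p = 0.253). Constant-region genes of antibodies held 1.25% ± 0.108 (SD, n = 3) of counts in females and 0.909% ± 0.0924 in males. Iglc1, a lambda light chain constant gene (chromosome 16, 19061618 to 19062071, GRCm38), fell by 1.43 on the log2 scale (SE 0.17), from 213 ± 53.3 to 79.9 ± 13.4 CPM, with Benjamini-Hochberg adjusted p = 2.23e-05 by edgeR's quasi-likelihood test. Ighg1, Igha and Ighg2b fell by 1.19, 0.97 and 0.68 on the log2 scale; constant genes of a class resemble each other, so reads could be shared between them. The most abundant of them, Igkc, had a log2 fold change of -0.38 ± 0.14 and did not pass. Pou2af1, a coactivator of B cells, fell by 1.96, and Ncam1 and App, genes of cell surface proteins, fell by 2.29 and 0.80.

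Of the 11 tested genes of antigen presentation by MHC class II, 3 fell, none rose and 8 did not pass (5 fell adjusted over the list alone); 4 of the 11 fold changes lay above 0. Cd74, the invariant chain of class II molecules, fell from 132 ± 16.7 to 67.5 ± 21.9 CPM (n = 3 each), and H2-Aa and H2-Eb1, chains of the molecule itself, fell by 1.36 and 1.37 on the log2 scale. The list was lower in males (camera, adjusted p = 5.16e-04), a call lost with an estimated correlation (adjusted p = 0.273). Without male replicate 3 the falls of Cd74, H2-Aa, H2-Eb1, Ms4a1, Pou2af1, Ncam1, App and Ighg2b did not pass; their adjusted p by edgeR's quasi-likelihood test reached 0.101 for Cd74, 0.128 for Ms4a1, 0.105 for Pou2af1, 0.124 for Ncam1, 0.108 for App and 0.122 for Ighg2b. Without female replicate 2, Cd74, Ms4a1, Pou2af1 and Ighg2b did not pass either, and H2-Aa and H2-Eb1 had their highest adjusted p, 0.159 and 0.231. Pou2af1 and H2-Eb1 also did not pass without female replicate 3, Ighg2b without female replicate 1, and H2-Eb1 without male replicate 2. By DESeq2 and by limma-voom, H2-Aa, H2-Eb1, Ms4a1, Pou2af1 and Ncam1 did not pass, with DESeq2's adjusted p at 0.0628, 0.130, 0.132, 0.175 and 0.0953.

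Of the 6 tested X-linked genes known to escape inactivation, 1 fell and 5 did not pass (3 fell adjusted over the list alone), and all 6 fold changes lay below 0. Eif2s3x, the X-linked partner of Eif2s3y, fell from 76.2 ± 6.08 to 40.9 ± 8.09 CPM (n = 3 each; Benjamini-Hochberg adjusted p = 0.0126 by edgeR's quasi-likelihood test, up to 0.0875 without female replicate 3, and not passed without female replicate 2, male replicate 2 or male replicate 3, or by DESeq2, 0.0716). Kdm5c and Kdm6a, histone demethylase genes, had log2 fold changes of -0.76 ± 0.18 and -0.78 ± 0.23 and did not pass, and neither did Ddx3x (-0.26 ± 0.13), 5530601H04Rik (-0.40 ± 0.26) or Pbdc1 (-0.14 ± 0.15). The list was lower in males (camera, adjusted p = 6.94e-06), a call lost with an estimated correlation (adjusted p = 0.134). Over the 249 tested genes of the X chromosome, none rose and 2 fell, Xist and Eif2s3x. Ftx, another RNA of the X-inactivation centre, had a log2 fold change of -0.22 ± 0.38.

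None of the 11 tested genes of the aldehyde dehydrogenase family passed the test, nor did any when adjusted over the list alone. At an unadjusted level of 0.05, edgeR called 959 of all tested genes and DESeq2 499; in the family, edgeR called only Aldh1a1. Aldh2, the most abundant, had 406 ± 36.0 CPM in females and 453 ± 41.8 in males (n = 3 each). Aldh9a1 had 182 ± 20.96 and 166 ± 21.2 CPM. Aldh1a1, the isoform most often linked to this kind of sort, had 7.99 ± 2.54 and 16.4 ± 6.82 CPM, with a log2 fold change of 0.97 ± 0.38. The fold changes of Aldh4a1, Aldh1b1, Aldh16a1, Aldh18a1, Aldh3a2, Aldh3b1, Aldh6a1 and Aldh7a1 lay between -0.40 and 0.12 on the log2 scale, and those of Aldh6a1 and Aldh7a1 changed sign when scaled by library size only. The family as a list did not differ (camera, adjusted p = 0.877). Dhrs3 and Rxrb, of the 4 tested genes of retinoid handling, had log2 fold changes of 0.07 ± 0.14 and 0.05 ± 0.15.

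The 76 tested genes of cytosolic ribosomal proteins all had fold changes above 0, and none passed the gene test (46 rose adjusted over the list alone). Their share of counts was 12.1% ± 0.519 (SD, n = 3) in females and 14.4% ± 1.95 in males, with 12.4%, 16.3% and 14.6% in male replicates 1, 2 and 3; male replicate 2 stood apart from the other libraries on the first principal component and had the lowest total count. Rps12 and Rpl4 had log2 fold changes of 0.39 ± 0.15 and 0.24 ± 0.14. The list was higher in males (camera, adjusted p = 5.96e-25), a call lost with an estimated correlation (adjusted p = 0.435). None of 43 nuclear genes of oxidative phosphorylation passed, with Atp5b at -0.01 ± 0.12 and Atp5a1 at 0.05 ± 0.12, while the list was higher in males (camera, adjusted p = 5.03e-07; adjusted p = 0.485 with an estimated correlation, and 0.0503 without male replicate 2). Of 12 mitochondrially encoded genes, mt-Co1 rose by 0.67 ± 0.15 (a call kept only with male replicate 1 left out, not kept by limma-voom, and with an adjusted p of up to 0.249 by edgeR's quasi-likelihood test, without male replicate 3) and 11 did not pass (2 rose adjusted over the list alone), among them mt-Rnr2 (0.83 ± 0.24) and mt-Rnr1 (-0.53 ± 0.36). That list was higher in males too (camera, adjusted p = 1.40e-04; adjusted p = 0.435 with an estimated correlation), and mitochondrial ribosomal RNA took 5.27% of the counts of male replicate 2.

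The 5 tested stromal and osteolineage markers were higher in males as a list (camera, adjusted p = 0.0259), although none passed alone (2 adjusted over the list alone), and the call was lost with an estimated correlation (adjusted p = 0.273), without male replicate 2 (0.268) and without female replicate 2 (0.136). Sparc, a matrix protein, had 31.4 ± 1.17 CPM in females and 51.0 ± 30.9 in males (n = 3 each), with 86.5 CPM in male replicate 2; Runx2, a regulator of bone formation, had 126 ± 11.9 and 109 ± 14.9 CPM. Genes of the lung epithelium were also counted in all 6 libraries, whose barcodes shared a pooled library with lung samples not analysed here. Sftpc, the gene of surfactant protein C, had 110, 108 and 68 raw counts in the female replicates and 88, 133 and 80 in the male ones. After scaling for depth its log2 fold change was 0.92 ± 0.23, higher in males, and it did not pass.

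**Figure D2:**
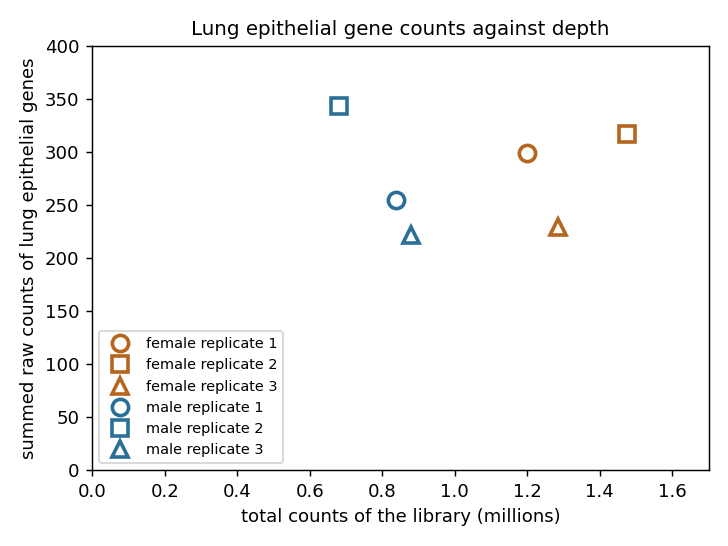
Summed raw counts of 13 lung epithelial genes (vertical axis) against the total counts of each library (horizontal axis), with a symbol for each of the 6 libraries. The sums were 299, 317 and 229 in the female replicates and 255, 343 and 222 in the male ones, while the totals ran from 679724 to 1475224.

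The remaining lists did not pass camera. Stem and multipotent progenitor markers had a median log2 fold change of 0.11 (camera, adjusted p = 0.105, although fry, which does not compare a list with other genes, gave 0.0162), with Cd48 at 0.36 ± 0.12. Immature granulocyte markers had a median of -0.0061 (adjusted p = 0.724), and monocyte, macrophage and dendritic cell markers one of -0.013 (adjusted p = 0.877; the test's direction was upward), with Ly6c2 at 0.04 ± 0.13 and F13a1 at -0.23 ± 0.12. Genes of S phase and of G2/M had adjusted p = 0.931 and 0.560 by camera, with Mcm6 at -0.0013 ± 0.12, Dut at 0.18 ± 0.12, Top2a at -0.03 ± 0.13 and Mki67 at -0.35 ± 0.18. Glycolysis genes (adjusted p = 0.560; Ldha 0.15 ± 0.12, Pkm 0.24 ± 0.13) and antioxidant genes (adjusted p = 0.877; Gpx1 0.03 ± 0.13, Tkt -0.0016 ± 0.13) did not pass either. Interferon-stimulated genes (adjusted p = 0.824; Bst2 0.10 ± 0.14, Gbp3 -0.10 ± 0.14), genes of sex-steroid receptors and metabolism (adjusted p = 0.280; Hsd17b12 -0.28 ± 0.14, Hsd17b10 0.19 ± 0.16) and angiogenic factors (adjusted p = 0.931; Tgfb1 -0.15 ± 0.13, Vegfb -0.33 ± 0.19) also fell short. Mature neutrophil markers (Csf3r -0.04 ± 0.18, Lcn2 -0.58 ± 0.39) and endothelial markers (Pecam1 0.16 ± 0.16, Eng 0.15 ± 0.20) had 3 tested genes each, too few for a test of the list, and none passed alone. Adjusted over the list alone, 1 antioxidant gene and 1 sex-steroid gene fell, 1 angiogenic factor rose, and none passed in the other lists of this paragraph. In total, 9 of 22 tested lists passed camera with its preset correlation, 3 of them also with an estimated one. At the preset correlation, splits of the 6 libraries that mixed the sexes also passed from 2 to 6 lists.

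**Figure D3:**
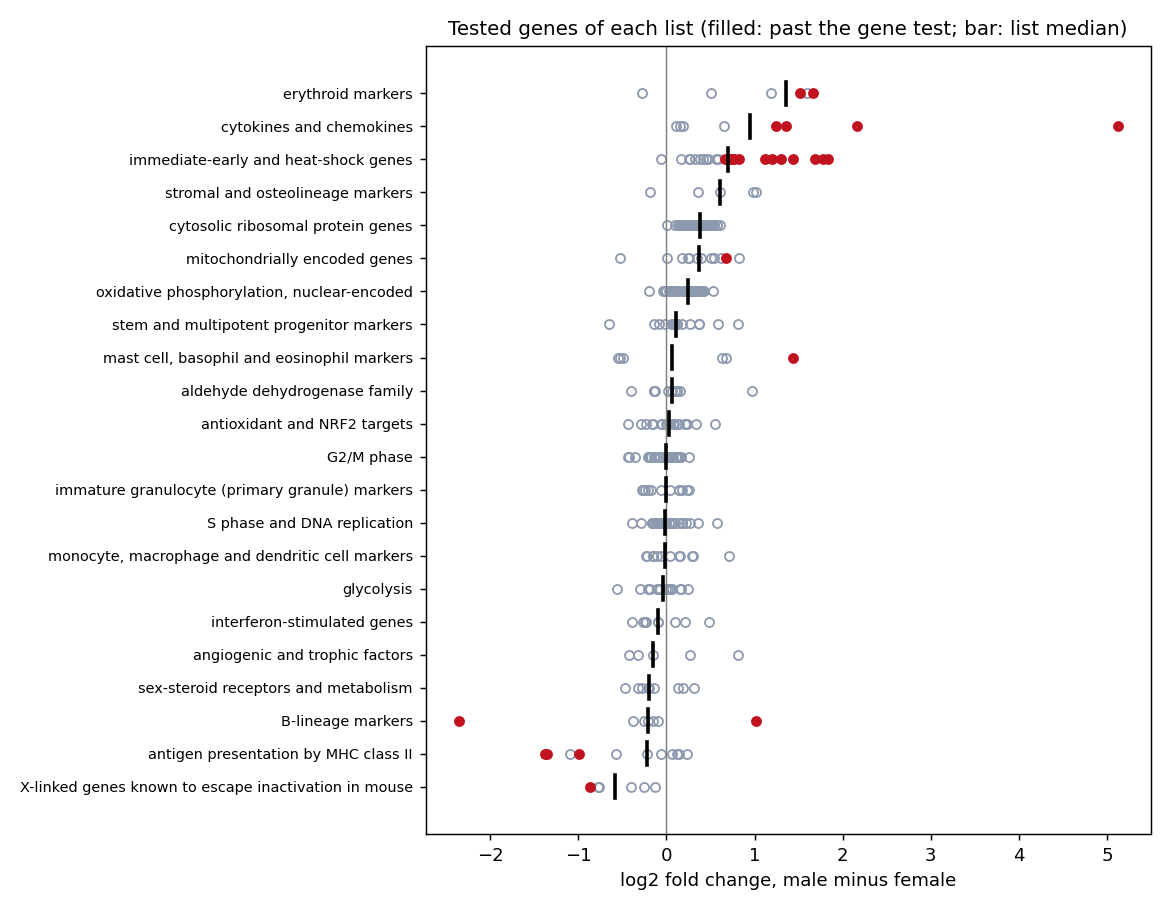
Log2 fold change, male minus female (horizontal axis), of each tested gene of the 22 lists that had at least 5 tested genes; filled points passed the gene test, open points did not, and the bar is the median of the list. Points of the immediate-early and heat-shock, cytokine and erythroid lists lie mostly to the right of 0, and all 6 of the X-linked escape genes lie to its left.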

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

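All 49 called genes kept their sign in every alternative in which they were tested. The stricter filter tested 47 of them and left out Cxcl2 and Tnfaip3, which had 7 and 9 counts in male replicate 2. In all 6 fits that left out a library 23 passed, and the other 26 did not pass without male replicate 3. Of the 49 calls, DESeq2 kept 37, limma-voom 41, library size only 41 and thinning 38. Among the genes named in the text, the calls lost by DESeq2 were Pou2af1, Ms4a1, Ncam1, H2-Aa, H2-Eb1, Eif2s3x, Tnf and Dnajb1, and by limma-voom Pou2af1, Ms4a1, Ncam1, H2-Aa, H2-Eb1, Tnfaip3 and mt-Co1. Library size only lost Tnf, Dnajb1 and Zfp36; thinning lost Tnf, Dnajb1, Tnfaip3, mt-Co1, H2-Aa, H2-Eb1 and Eif2s3x; sample weights lost H2-Eb1; and the cause was not tested. Leaving out a library moved the genes higher in males to between 19 and 332 and those higher in females to between 4 and 77. Those off the sex chromosomes moved to between 19 and 390, and the lists past the test to between 7 and 9. Without male replicate 1 all 49 calls were kept among 409. The cause of these moves was not tested. In log2 CPM, male replicate 1 had a mean correlation of 0.956 with the other male libraries and 0.965 with the female ones. For male replicate 2 these were 0.952 and 0.945, and for male replicate 3 they were 0.9604 and 0.9607. Each female library correlated better with its own sex. Genes higher in males and in females and genes off the sex chromosomes numbered 81, 35 and 106 with no filter, where more genes are tested; 101, 20 and 110 by limma-voom with sample weights; 59, 22 and 74 at an adjusted p under 0.10; and 22, 8 and 26 with a log2 fold change beyond 1. Genes higher in females numbered 23 with library size only, 7 by DESeq2 and 8 by limma-voom; the cause was not tested. With an estimated correlation 3 lists passed, and by fry 5, of which stem and multipotent progenitor markers (adjusted p = 0.0162) had not passed camera. With the stricter filter, and by limma-voom with sample weights, 8 of the 9 lists passed camera, and with no filter 10 lists did. With the replicate number as a block, 56 genes were higher in males, 22 in females and 70 lay off the sex chromosomes. That fit kept all 49 calls, and 9 lists passed. The deviations of same-numbered libraries correlated at 0.030, 0.034 and 0.048. These values are low, but every library correlated best with the library of its own number in the other sex. No bound was set for them, so whether the numbers mark pairs stays open. Of the other values, 1413 of named genes and 421 of lists kept direction and side of the threshold, 57 and 15 no longer passed, 14 and 2 newly passed, and 60 and 22 changed sign. None of those that changed sign passed in either setting; their adjusted p was at least 0.729 for genes and 0.217 for lists. In log2 fold change these were Mcm6 (0.0022) and Tkt (0.0023) with RLE; Aldh7a1 (-2.5e-04) and Actb (-0.0023) with upper-quartile factors; Aldh6a1 (-0.021), Aldh7a1 (-0.070), Dhrs3 (-0.018), Rxrb (-0.038), Ly6c2 (-0.066), Bst2 (-0.0012), Atp5a1 (-0.047), Gpx1 (-0.068) and Actb (-0.077) with library size only, which shifted the median of all genes by -0.089. Further ones were Aldh7a1 (-0.015) and Actb (-0.015) with no filter, Mcm6 (0.0058) and Tkt (0.0055) with the stricter filter, and Mcm6 (0.0028) and Tkt (0.0018) by DESeq2. By limma-voom with sample weights they were Aldh18a1 (-0.036), Aldh6a1 (-0.050), Aldh7a1 (-0.15), Mcm6 (0.013), Top2a (0.060), Gpx1 (-0.0034) and mt-Rnr1 (0.022), and after thinning Aldh3b1 (0.50), Aldh7a1 (-0.28) and Tkt (0.0025). Lists that changed direction did so at adjusted p = 0.946 (monocyte markers), 0.999 (angiogenic factors) and 0.932 (antioxidants) with library size only, 0.930 (monocyte markers) and 0.217 (angiogenic factors) with no filter, and 0.967 (aldehyde dehydrogenases), 0.969 (monocyte markers) and 0.969 (S phase) with the stricter filter. The others were aldehyde dehydrogenases by limma-voom with sample weights (0.940), interferon-stimulated genes after thinning (0.903) and S phase by fry (0.968). With single libraries left out, log2 fold changes that crossed 0 ranged from -0.31 to 0.095 for Aldh3b1, -0.13 to 0.022 for Csf3r, -0.66 to 0.037 for Ftx, -0.071 to 0.043 for Atp5b, -0.11 to 0.082 for Tkt, -0.15 to 0.28 for Aldh6a1, -0.22 to 0.22 for Aldh7a1, -0.029 to 0.13 for Ly6c2, -0.045 to 0.060 for Mcm6, -0.15 to 0.087 for Top2a, -0.029 to 0.047 for Actb, -0.97 to 0.029 for mt-Rnr1, -0.24 to 0.014 for Pbdc1, -0.027 to 0.21 for Aldh16a1, -0.0069 to 0.27 for Aldh18a1, -0.056 to 0.27 for Bst2 and -0.082 to 0.097 for Gpx1. The adjusted p of lists that changed direction there ranged from 0.825 to 0.999 for angiogenic factors, 0.371 to 0.961 for interferon-stimulated genes, 0.569 to 0.999 for aldehyde dehydrogenases, 0.541 to 0.999 for monocyte markers, 0.878 to 0.963 for S phase, 0.607 to 0.944 for antioxidants and 0.295 to 0.973 for immature granulocyte markers; the cause of these sign changes was not tested. At this depth, 29.9% of simulated genes changed by 0.5 on the log2 scale were recovered, so smaller differences can be missed.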

Other observations

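Beyond the lists of the report, 18 of the 20 tested plasma cell genes had fold changes below 0, and 5 fell in males (camera, adjusted p = 4.52e-11; adjusted p = 0.0513 with an estimated correlation). Of the 10 tested constant-region genes of antibodies, all lay below 0 and 4 fell. Of 6 mature B cell genes 1 fell (camera, adjusted p = 0.0240; adjusted p = 0.135 with an estimated correlation), and of 11 early B and lymphoid progenitor genes only Dntt rose (camera, adjusted p = 0.185). Of 16 tested erythroid and megakaryocyte progenitor genes 3 rose (camera, adjusted p = 4.15e-06; adjusted p = 0.0659 with an estimated correlation). These lists were written after the data were seen, and the plasma cell list holds genes already called. All tests below were chosen after the patterns were seen; for plasma cells, mature B cells and progenitors the bounds were set before the values they measure.

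Immediate-early, heat-shock and chemokine genes were higher in males, with a median log2 fold change of 0.69 over 32 tested genes, of which 17 passed. Raw male to female ratios cannot tell whether RNA of the lung samples in the pooled library is the source. Over all 32 genes the ratio was 0.8405 (0.826 to 0.855) and the median of their own ratios 0.928 (0.778 to 1.23). For lung epithelial genes it was 0.9704 (0.880 to 1.07). Amounts per library argue against lung RNA as the main source for the immediate-early and heat-shock list. Summed lung epithelial genes had 249, 215 and 178 CPM by library total in female replicates and 304, 505 and 252 in male ones. The list held 0.738%, 0.671% and 0.697% of counts in females and 1.08%, 0.784% and 1.01% in males. Its share was thus lowest in the male library with most lung RNA. For the chemokines a lung source stays open. Of the 32, 9 had intervals above the lung one, and for 3 the interval adjusted over the 32 lay above 1.498, the highest lung ratio of a male to a female library, but these are top genes of the pattern with counting error only: Ccl4, Cxcl2 with 2 counts in females, and Hspa1b, where male replicate 1 held 310 of 629 male counts. A larger share of monocytes or macrophages stays open, since 12 markers had a median of -0.013 (-0.15 to 0.22) with 6 on either side of 0, Ly6c2, at 2045 CPM in females, is too abundant to show a small share, and the sparse Adgre1 had 7.47 CPM in females and 12.8 in males (log2 fold change 0.71 ± 0.41, not passed). Cells sorted or handled at different times may also raise such genes, and 0 labels give a day or batch, so handling and a difference between the sexes, itself untested, both stay open.

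In males 4 of 10 tested constant-region genes of antibodies and 3 of 11 tested MHC class II genes fell, while 4 of the 11 lay above 0 and the call of the list was lost with an estimated correlation (adjusted p = 0.273). Fewer plasma cells among the male cells remain possible. The 5 tested genes set for this explanation, none an immunoglobulin, were Jchain, Mzb1, Sdc1, Fkbp11 and Pou2af1. They had a median of -0.44 (bootstrap 95% interval -1.96 to -0.091), and the interval spans the bound of -0.54. That bound was set from the median of the 4 called constant-region genes (-1.08). All 10 tested ones had a median of -0.53, so a bound set from them would be easier to meet. Pou2af1 (-1.96) was already called, and the others did not pass. Other genes of the plasma cell list that are not immunoglobulins lay above the bound. These were Ssr4 (0.47), Xbp1 (0.016), Creld2 (-0.015), Edem1 (-0.14) and Txndc5 (-0.32). Fewer mature B cells also stay open, with a median of -0.22 (-1.42 to 0.18) over 6 genes against a bound of -0.4. Both tests rest on few genes and cannot be told apart from each other or from an untested difference between the sexes; Igkc, the most abundant antibody gene, had 7496 CPM in females and 5760 in males.

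Summed raw counts of lung epithelial genes ran from 222 to 343 per library and followed depth poorly: their male to female ratio was 0.9704 (95% interval 0.880 to 1.07, counting error only) where library totals had 0.605. RNA or misread barcodes from the 10 lung samples of the pooled library may be the source, but the sums differed between libraries by more than counting error, less so against equal counts (chi-square 44.1, 5 df) than against counts in proportion to depth (chi-square 207), so this stays open. Of the 13 genes 6 were tested, and none passed, but all 6 had log2 fold changes above 0. Their median was 0.76 (bootstrap 95% interval 0.38 to 1.03), against 0.69 for the immediate-early, heat-shock and chemokine genes. As a list they were higher in males (camera, adjusted p = 1.04e-05, and 0.135 with an estimated correlation). Whether such RNA raised the stromal and osteolineage markers cannot be told apart: their ratio was 0.687 (0.616 to 0.766), but 0.981 (0.835 to 1.15) without Runx2, which holds most of their counts and did not rise. No biological explanation was tested for the lung epithelial genes or for the stromal and osteolineage markers.

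A further hypothesis was that Car1, Car2, Pf4 and Cpa3 were higher because of more erythroid and megakaryocyte progenitors among the male cells. The other 13 tested genes of such progenitors had a median log2 fold change of 0.055 (bootstrap 95% interval -0.11 to 0.14). The interval lay under the bound of 0.3, which was the outcome set before as counting against this explanation. Leaving out the called Car1, Car2 and Pf4 kept the test apart from the genes to be explained. That choice lowered the median from 0.092 to 0.055, and both values lie under the bound. Over all 16 tested genes the median was 0.092 with an interval from -0.080 to 0.97, which spans the bound. This wider check was not part of the rule set before. It holds Car1, Car2 and Pf4, the genes to be explained, so it cannot decide the question. The largest change among the 13 was that of Ermap, at 1.596 ± 0.40, which did not pass (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0722). By the rule set before, the 13 genes as a set counted against more such progenitors. Of them 8 lay above 0 and 5 below, and a median does not exclude a rise of only some, such as Ermap. More such progenitors and a change in Car1, Car2, Pf4 and Cpa3 alone, an untested difference between the sexes included, therefore cannot be fully told apart.

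The 6 samples can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split alone, 1 of the 10, gave as many calls for each count. It gave 36 genes higher in males and 13 in females, where no other split gave more than 3 in a direction. Off the sex chromosomes it gave 44 genes, where the highest other had 4. It gave 9 lists, where every other split also gave lists, from 2 to 6. Apart from the split that put female replicates 1 and 2 with male replicate 1, those other splits called 0 genes. Lists thus passed camera at the preset correlation where no gene passed, so its small adjusted p overstate the evidence for a list.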
